A study of Homo sapiens with 323 samples.

How the data were processed

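Counts, per the labels, were reads per gene from the deposited count tables, with 1 row per gene symbol (26485) or, for the tumours, per gene identifier (60279, of which 56104 carried a symbol). Peak scores, per the labels, were the deposited scores of the peak caller and were used only within a list. The deposited peak positions are the authors' other unit, intervals in base pairs on hg38. The submitters' notes describe alignment to hg38 with STAR 2.6.0 and counting with HTSeq for RNA, and Bowtie 0.12.9 with MACS 1.4.2 for ChIP-seq, with FastQC 0.11.2 for quality. The gene annotation is not stated. RNA libraries were made with QuantSeq FWD (239), QuantSeq Pool (12) and NEBNext Ultra II (27), and ChIP-seq libraries with KAPA HTP (45). The analysis started from the deposited counts and peaks. Of the 45 ChIP-seq samples, 12 had a list of their own, 4 stood behind 2 merged lists and 29 had none analysed here.

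Gene tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3: TMM factors, the default filter on low counts, a quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Standard errors were the fold change divided by the square root of F. CPM values used library sizes scaled by TMM, and log2 CPM a prior count of 2. In the siRNA panel the counts of replicates were summed per line and arm, and the line was a block, for 11 lines, or 7 where both siRNAs were tested. The 2 further PC3M models were added only as an alternative. In the CRISPR panel the guides of a target were summed within a line, the PC3M clones X1 and X2 were summed as 1 line, and controls were cells without a guide (BT20, H838, PC3M), with sgNon-Targeting (LNCaP, MCF7) or with sgAAVS1 (MDAMB231). The heat, stress, knockout, overexpression and tumour experiments each had a fit of all their groups, with interaction terms as differences between responses. Replicate letters were not used as pairs: where letters recur between groups, no experiment had a correlation of residuals over 0.1 in every pair, and the PC3M tumours, whose usable letters do not recur, had no such check.

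Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The 16 lists, written before the data were examined, were cytosolic and mitochondrial chaperones (34 genes), CCT chaperonin (8), proteasome (31), ER chaperones (20), ATF4 targets (18), hypoxia targets (21), mitotic genes (20), DNA replication genes (24), cytosolic tRNA synthetases (18), cholesterol synthesis (18), serum response and YAP targets (18), interferon response (20), p53 targets (15), extracellular matrix and adhesion (22), markers of stromal, endothelial and immune cells (23) and mitochondrially encoded transcripts (13, present in the tumour tables alone). The first list also holds the ubiquitin genes UBB and UBC and the ER chaperone SERPINH1, and counts of chaperones include them. The comparisons, lists, alternatives and the rule for naming genes were also set before the data were examined. That rule names HSF1 and HSF2 first. Among genes past adjusted p 0.05 with a mean log2 CPM of at least 3 that moved the same way in every line, or whose groups did not overlap, it names the 6 largest rises and the 6 largest falls. It adds up to 4 members of each list past the threshold with the largest change, and 8 chaperones fixed beforehand (HSPA1A, HSPA8, HSPH1, DNAJB1, HSP90AA1, HSPD1, HSPE1 and BAG3). Further contrasts within the heat, stress, overexpression and tumour experiments were chosen after the first results were seen.

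The agreement of HSF1 and HSF2 fold changes used separate siNon-Targeting libraries for each arm, with 20 simulations of unchanged arms drawn at the fitted dispersions. Peak work used bedtools 2.31.1: regions were the merged peaks of both lists wherever peaks of the 2 overlap by at least 1 bp, and intervals were exact binomial. Chance overlap came from 1000 random placements. A gene was bound when its start site, of 26484 genes with 1, lay within 1 kb of a region, and 5 kb was the alternative. Bound genes were tested with camera. Other software was DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

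The procedure was tried on sets with a known answer, in which 200 genes were changed in simulated counts of the same sizes, 100 of them by 1.5-fold and 100 by 2-fold. It recovered 90 and 100 of 100 in the siRNA panel with HSF1, 65 and 95 in the CRISPR panel with HSF2, 26 and 62 in the heat experiment, 66 and 90 under serum starvation, 26 and 74 in PC3M tumours with HSF2 guides and 70 and 94 with HSF2-Flag. Interactions recovered 36 and 90 (siRNA panel), 6 and 39 (heat), 32 and 75 (serum starvation) and 19 and 74 (overexpression). MDAMB231 knockout cells gave 0 and 9 and MDAMB231 tumours 0 and 37, so a change of 2-fold would mostly be missed there. The list test was tried only in the siRNA panel with HSF1, on lists of 20 genes. There it called 5 of 5 lists shifted by 1.2-fold and 0 of 5 unchanged lists.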

Results

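The series examined HSF1 and HSF2, a pair of heat shock transcription factors, in human cancer cell lines and in tumours that these lines formed in immunocompromised mice. Of its 323 samples, 278 were RNA libraries with a column of read counts and 45 were chromatin immunoprecipitation (ChIP-seq) samples. The siRNA panel held 108 libraries in 46 groups of 2 to 3, with a non-targeting small interfering RNA (siNon-Targeting), siHSF1, siHSF2 or both. Its lines came from breast cancer (MCF7, SKBR3, BT20, HCC38, ZR751, MDAMB231), prostate cancer (PC3M, LNCaP, VCaP) and lung cancer (H838), and the labels give no tissue for DLDTIR1. The CRISPR panel held 60 libraries in 26 groups of 2 to 4 from 6 of these lines, with guide RNAs (sgRNA) against HSF1 or HSF2. MDAMB231 cells supplied a heat shock experiment (12 libraries in 6 groups of 2) and a stress experiment (47 libraries in 16 groups of 2 to 3). MCF7 cells supplied an overexpression experiment (24 libraries in 8 groups of 3). MDAMB231 supplied 10 tumours in 3 groups of 2 to 4, and PC3M 17 tumours in 5 groups of 2 to 6. The labels do not say whether lettered replicates were separate cultures, so they may be technical.

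Depth differed between experiments. A siRNA panel library held 468215 to 21742980 counts (median 2441566) over 11897 to 15828 detected genes, and a CRISPR panel library 580681 to 10248522 (median 1617341) over 11787 to 14374 genes. Heat shock libraries held 1530541 to 3561869 counts, stress libraries 924068 to 6858910, and overexpression libraries 1810307 to 11865664. MDAMB231 tumours held 3002186 to 8253243 counts and PC3M tumours 2886558 to 10854684. No replicate pair was a copy: among 236 pairs the lowest chi-square per degree of freedom was 1.26. Values after ± below are standard errors of log2 fold changes, and intervals of shares cover counting error only. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, and gene lists with camera at a preset correlation between genes.

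Both siRNAs lowered the RNA of their target in every line. HSF1 RNA under siHSF1 ranged from 6.89% (DLDTIR1) to 30.6% (MCF7) of the level under siNon-Targeting in the same line. HSF2 RNA under siHSF2 ranged from 13.3% (H838) to 30.3% (MDAMB231). Under both siRNAs, HSF1 lay between 7.50% (PC3M) and 24.8% (LNCaP) and HSF2 between 12.5% (H838) and 39.4% (LNCaP). HSF1 was most abundant in PC3M, with 865 CPM (counts scaled by library size) in the control arm against 68.3 (DLDTIR1) to 227 (ZR751) in the other lines.

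The siHSF1 arm of 11 lines was set against the siNon-Targeting arm to ask which genes depend on HSF1. HSF1 itself was 6.98-fold lower (log2 fold change -2.80 ± 0.16), and cytosolic and mitochondrial chaperones fell with it. Of 32 chaperone genes measured, 19 fell and none rose (21 fell when adjusted over the list alone). HSPH1, an HSP110 cochaperone, fell by 0.92 ± 0.10, HSP90AA1, the inducible HSP90, by 0.62 ± 0.086, DNAJB1, an HSP40 cochaperone, by 0.47 ± 0.10, and HSPD1, the mitochondrial HSP60, by 0.33 ± 0.072, in 11 of 11, 10 of 11, 10 of 11 and 11 of 11 lines. SERPINH1, the collagen chaperone of the endoplasmic reticulum (ER), is counted in this list too and changed by -0.95 ± 0.16 (adjusted p = 0.000342), lower in 11 of 11 lines. Mitotic genes fell as a group, 18 of 20 (19 adjusted over the list alone), among them TOP2A (-0.84 ± 0.11, adjusted p = 9.2e-06) and the kinase AURKA (-0.74 ± 0.13, adjusted p = 0.000498), both lower in 11 of 11 lines. DNA replication genes fell in 13 of 24 cases (16 adjusted over the list alone), with the helicase subunit MCM6 at -0.62 ± 0.092. The largest falls outside the lists were ARHGAP18 (-1.59 ± 0.19) and KDELR1, a receptor that returns proteins to the ER (-1.25 ± 0.22), and the largest rise was the kinase PSKH1 (1.27 ± 0.18). PSKH1 was also higher under siHSF2, by 0.23 (LNCaP) to 1.92 (H838) in single lines, so its rise was not particular to siHSF1.

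Camera called the chaperones (adjusted p = 5.2e-16), mitotic genes (5.4e-29) and replication genes (1.7e-18) lower, and all 3 held with an estimated correlation (adjusted p = 0.00349, 0.00349 and 0.00370). Of 8 subunits of the cytosolic chaperonin CCT, 4 fell (5 adjusted over the list alone), and of 20 ER chaperones 4 fell (6 adjusted over the list alone), with the disulfide isomerase PDIA4 at -0.81 ± 0.11. With an estimated correlation these lists were not called (adjusted p = 0.111 and 0.165). HSPE1, the mitochondrial HSP10, fell by 0.54 ± 0.15 (adjusted p = 0.0240), with adjusted p = 0.0575 without MCF7 and 0.0595 without PC3M. In all, 456 of 11763 genes rose and 589 fell. The count of 1045 became 653 without BT20, 659 without PC3M, 679 without MCF7 and 682 without SKBR3, and 1542 with 2 further PC3M models added.

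The siHSF2 arm of the same lines asked the same question of HSF2. HSF2 was 4.64-fold lower (-2.21 ± 0.10), and far fewer genes passed the test than under siHSF1: 23 rose and 37 fell. HSF1 RNA was also lower in most lines of this arm, with log2 fold changes from -1.07 (BT20) and -0.75 (PC3M) to 0.08 (DLDTIR1). The part of lower HSF1 in the changes of this arm was not tested. DCPS, the scavenger decapping enzyme, changed by -0.89 ± 0.10 (adjusted p = 7.2e-06), MZT1, a part of the gamma-tubulin ring complex, by -0.85 ± 0.14, the small GTPase RAB28 by -0.83 ± 0.15 and the nucleotide sugar transporter SLC35B4 by -0.85 ± 0.13, each lower in 11 of 11 lines. Among 32 chaperones 3 fell (8 adjusted over the list alone), and 27 of the 32 had a fold change below 0. HSPH1 fell by 0.56 ± 0.10 in 10 of 11 lines, and HSPE1 by 0.77 ± 0.15 in 11 of 11 (adjusted p = 0.0126). For HSP90AA1 the value was -0.30 ± 0.085 (adjusted p = 0.110) and for HSPD1 -0.27 ± 0.072 (adjusted p = 0.0852), lower in 11 of 11 lines without passing the threshold. Of 8 CCT subunits 1 fell (4 adjusted over the list alone), and of 17 genes of cholesterol synthesis none passed over all genes (1 lower adjusted over the list alone) although 16 lay below 0. Camera called these 3 lists lower (adjusted p = 5.9e-07, 2.2e-05 and 2.5e-07), with adjusted p = 0.0657 for each with an estimated correlation. The HSPE1 call ended without HCC38, MCF7, BT20 or ZR751 (adjusted p = 0.0503, 0.0662, 0.0505 and 0.0645). The total of 60 genes moved to 20 without HCC38, 16 without MCF7, 20 without SKBR3, 20 without BT20, 37 without PC3M, 18 without ZR751 and 33 without H838, and was 184 by DESeq2 and 161 with 13 models.

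**Figure D1:**
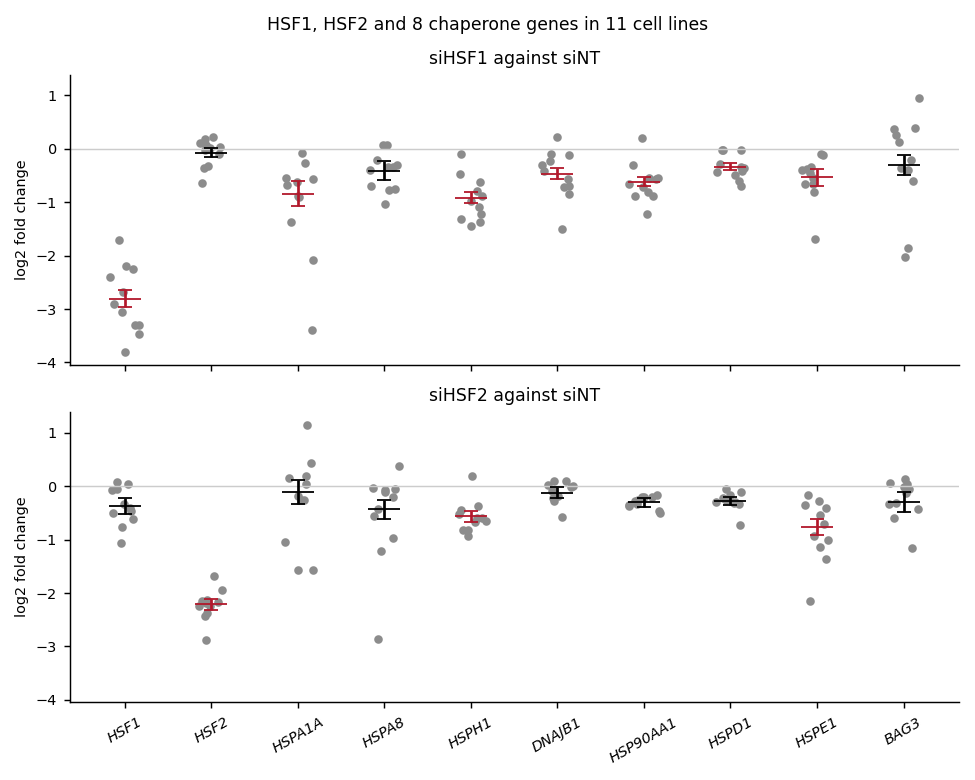
Log2 fold changes of HSF1, HSF2 and 8 chaperone genes between the siRNA arms and the siNon-Targeting arm, with 1 point per cell line of the 11 in the panel. HSPH1 lay below 0 in 11 of 11 lines under siHSF1 and in 10 of 11 under siHSF2.

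A direct test between the siHSF1 and siHSF2 arms showed where the depletions differed. Mitotic genes were lower under siHSF1 than under siHSF2 in 15 of 20 cases (18 adjusted over the list alone), with TOP2A at -0.89 ± 0.11 and AURKA at -0.73 ± 0.13, and replication genes in 10 of 24 (15 adjusted over the list alone). Cholesterol synthesis went the other way, with 9 of 17 genes higher under siHSF1 (11 adjusted over the list alone), including MVK (0.66 ± 0.12), the isomerase IDI1 (0.59 ± 0.11) and the demethylase CYP51A1 (0.57 ± 0.095). SERPINH1 (-0.91 ± 0.16) and PDIA4 (-0.69 ± 0.11) were lower under siHSF1. HSPD1 (-0.059 ± 0.072, adjusted p = 0.691) and HSPE1 (0.23 ± 0.15, adjusted p = 0.400) did not differ detectably. The mitotic, replication and cholesterol lists were called also with an estimated correlation (adjusted p = 0.0223, 0.0474 and 0.0254). Of 32 chaperones 9 were lower under siHSF1 (11 adjusted over the list alone), a call with adjusted p = 0.105 with an estimated correlation. In total 381 genes were higher under siHSF1 and 557 lower, and the 938 became 605 without SKBR3 and 484 without BT20.

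In 7 lines (BT20, PC3M, H838, DLDTIR1, VCaP, LNCaP and MDAMB231) both siRNAs were used together. HSF1 (-2.99 ± 0.20) and HSF2 (-2.14 ± 0.15) were both lower, and 14 of 33 chaperones fell (16 adjusted over the list alone). HSPH1 fell by 1.21 ± 0.14, HSP90AA1 by 0.88 ± 0.11 and HSPD1 by 0.42 ± 0.081, each lower in 7 of 7 lines. Mitotic genes fell in 9 of 20 cases (19 adjusted over the list alone), with TOP2A at -0.76 ± 0.12 and CDC20 at -0.62 ± 0.095, and replication genes in 7 of 24 (13 adjusted over the list alone), with thymidylate synthase TYMS at -0.62 ± 0.090. INSIG1, a regulator of sterol synthesis (-0.89 ± 0.14), and MDM2, the ubiquitin ligase of p53 (-0.60 ± 0.11), were also lower in 7 of 7 lines. The chaperone, mitotic and replication lists held with an estimated correlation (adjusted p = 0.0129, 0.0191 and 0.0286). Of 12818 genes 53 rose and 160 fell. The 213 became 122 without DLDTIR1, 73 without VCaP, 103 without LNCaP, 91 without BT20, 80 without PC3M and 102 without MDAMB231, and DESeq2 called 506 with 190 higher.

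Whether losing HSF2 adds to losing HSF1 was asked by setting both siRNAs against siHSF1 alone. HSF2 was the only gene called (-2.04 ± 0.15, lower in 7 of 7 lines), and HSP90AA1 (-0.30 ± 0.11), HSPE1 (-0.31 ± 0.20) and HSPH1 (-0.34 ± 0.14) lay below 0 without passing. Cholesterol synthesis genes lay below 0 in 17 of 18 cases (none called over all genes, 2 lower adjusted over the list alone), a camera call (adjusted p = 3.4e-06) with adjusted p = 0.278 with an estimated correlation. DESeq2 called 2 genes. The departure of the double knockdown from the sum of the single knockdowns gave no gene in edgeR (135 at unadjusted p under 0.05) or in DESeq2. For HSPH1 it was 0.15 ± 0.19 and for HSP90AA1 0.016 ± 0.16. Camera called 5 lists above 0 for this term: chaperones (26 of 33 genes above 0, adjusted p = 0.0168), CCT (7 of 8, 0.0317), mitotic genes (17 of 20, 0.0261), replication genes (16 of 24, 0.0466) and serum response genes (12 of 18, 0.00463), with no gene called over all genes or adjusted over a list alone and adjusted p = 0.727 for each with an estimated correlation. The chaperone call ended without LNCaP (0.0686) or PC3M (0.214), CCT without PC3M (0.214), H838 (0.0691) or MDAMB231 (0.0580), mitotic without VCaP (0.0509) or PC3M (0.215), replication without VCaP (0.0839), BT20 (0.131), PC3M (0.262) or MDAMB231 (0.124), and serum response without LNCaP (0.0816).

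The HSF1 and HSF2 fold changes were then compared across genes, with the siNon-Targeting libraries divided so that each arm had its own controls. Over 11824 genes Pearson's r was 0.233 and Spearman's rho 0.235, genes not being independent replicates, and the jackknife standard error over lines was 0.0541. Simulated unchanged arms gave a mean r of 0.00228 and a highest of 0.0242. Both arms were still set against the same control siRNA, and the simulation held no effect of that siRNA. The observed r therefore does not separate shared regulation from such an effect, or from the lower HSF1 RNA under siHSF2. The covariance was 0.0128, above the simulated value by 0.0127. Among 1005 genes called for HSF1 and 102 for HSF2 in this division, 27 rose under both (2.46 by chance for independent lists), 11 fell under both (1.89 by chance) and 0 moved in opposite directions. With the same controls in both comparisons r was 0.390, against a mean of 0.502 in simulations without any effect.

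The CRISPR panel asked the same of edited cells of 6 lines (BT20, H838, LNCaP, MCF7, PC3M and MDAMB231). The libraries read the 3' end of transcripts, so an RNA level does not check an edit. HSF1 RNA was 37.6% of control in BT20, 25.3% in H838, 28.9% in LNCaP, 40.1% in MCF7, 6.94% in PC3M and 27.1% in MDAMB231. Of 33 chaperones 29 had a fold change below 0 and 5 fell (18 lower and 1 higher adjusted over the list alone). The 7 genes called were all lower: HSF1 (-2.03 ± 0.22), HSP90AA1 (-1.08 ± 0.14), HSPE1 (-0.93 ± 0.14), AHSA1, an activator of HSP90 (-0.63 ± 0.12), HSPA8, the constitutive HSP70 (-0.59 ± 0.11), the small heat shock protein HSPB1 (-1.11 ± 0.19) and PTOV1 (-0.54 ± 0.10). HSPB1 was lower in 5 of 6 lines and the others in 6 of 6. The chaperone list was called lower (adjusted p = 3.2e-32), also with an estimated correlation (adjusted p = 0.0318). Of 20 mitotic genes 16 lay above 0 and none was called, over all genes or adjusted over the list alone. The 7 became 2 without BT20, 3 without H838 and 2 without LNCaP, and HSF1 and HSP90AA1 alone kept their call whichever line was left out. The HSPE1 call ended without BT20 (adjusted p = 0.0614) or LNCaP (0.168), and the calls of AHSA1, HSPA8, HSPB1 and PTOV1 in 4 to 6 of the 6 omissions (0.0567 to 0.356). DESeq2 called 21.

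For HSF2 guides the RNA of the target did not follow the labels in every line. HSF2 RNA was 139% of control in BT20, 111% in PC3M, 84.3% in H838, 48.2% in LNCaP, 47.9% in MCF7 and 34.4% in MDAMB231. No gene was called by edgeR (444 at unadjusted p under 0.05) or by DESeq2, and HSF2 itself averaged -0.47 ± 0.28. HSP90AA1 (-0.46 ± 0.14) and HSPE1 (-0.48 ± 0.14) were below 0 in 6 of 6 lines of libraries labelled sgHSF2. Of 33 chaperones 20 lay below 0 (3 lower adjusted over the list alone), called lower by camera (adjusted p = 0.00770) with adjusted p = 0.808 with an estimated correlation and adjusted p = 0.166 without LNCaP.

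MDAMB231 cells also carried both guides together, with sgAAVS1, a guide to a safe-harbour site, as control and 3 libraries per group. HSF1 was at 113 to 118 CPM with sgAAVS1, 27 to 37 with sgHSF1.1, 38.5 to 43.6 with both guides and 103 to 124 with sgHSF2.1. HSF2 was at 25.1 to 30.6 CPM with sgAAVS1 and 8.06 to 12.4 with sgHSF2.1, but at 98.1 in the library labelled sgHSF1.1 B and at 76.6 and 72.2 in those labelled with both guides B and C. These 3 libraries stood apart from the other 9: in log2 CPM EEF1A1, a translation elongation factor, lay at 9.92 to 10.87 against 6.50 to 7.93 and S100A11 at 7.46 to 7.90 against 9.83 to 10.25. HSF1 was the only gene called under sgHSF1.1 (-1.80 ± 0.19) and under both guides (-1.52 ± 0.18). No gene was called under sgHSF2.1 by edgeR (345 at unadjusted p under 0.05, 7 genes by DESeq2), where HSF2 was -1.51 ± 0.57, nor for the departure from additivity (377 at unadjusted p under 0.05, 5 genes by DESeq2). For that departure camera called 9 lists, none with an estimated correlation (adjusted p = 0.0988 at the lowest); ER chaperones (adjusted p = 0.000511), ATF4 targets (2.9e-05, 5 higher adjusted over the list alone), cholesterol synthesis (0.000511) and serum response genes (0.000175) lay above 0 and kept their calls whichever library was left out. DESeq2 called 4 genes under sgHSF1.1 and 567 under both guides. With both guides the count moved from 1 to 2067 without replicate A of that group, the library that does not stand apart, and to 0 without its replicate B or C or any sgAAVS1 library, and without the 3 libraries that stand apart it was 0. Without those 3 the counts were 3 under sgHSF1.1 and 4 under sgHSF2.1.

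**Figure D2:**
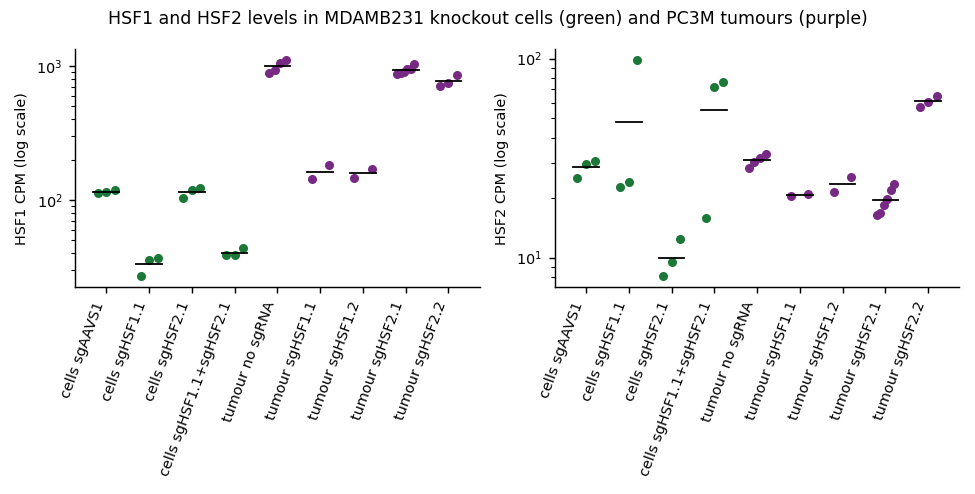
HSF1 and HSF2 RNA in CPM on a log scale, with 1 point per library for the MDAMB231 knockout cells (green) and the PC3M tumours (purple). HSF2 lay at 98.1, 76.6 and 72.2 in 3 MDAMB231 libraries and at 57.4 to 64.9 in the sgHSF2.2 tumours.

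Heat shock was applied to MDAMB231 cells without a guide, with sgHSF1.1 or with sgHSF2.1, to ask how the response depends on each factor; the labels give neither temperature nor duration. HSF1 RNA was 117 to 134 CPM without a guide and 36.8 to 48.9 with sgHSF1.1. HSF2 RNA was 50.8 to 71.8 CPM without a guide but 83.2 and 107 in unheated and 52.8 and 64.2 in heated libraries labelled sgHSF2.1. In cells without a guide 26 of 31 chaperones rose and none fell (27 rose adjusted over the list alone). HSPA6, an HSP70 made under stress, rose by 9.19 ± 0.22, the inducible HSP70 HSPA1A by 5.42 ± 0.14, DNAJB1 by 4.42 ± 0.12, the HSP70 cochaperone BAG3 by 3.16 ± 0.14 and HSPH1 by 3.14 ± 0.12 (adjusted p = 1.5e-23), each above both control libraries in 2 of 2. HSPA1A and HSPA1B are nearly identical copies, so counts may be split between them. Serum response genes fell in 7 of 18 cases and rose in 2 (10 and 2 adjusted over the list alone), the transcription factors EGR1 by 2.44 ± 0.15 and KLF6 by 1.77 ± 0.12, while the phosphatase DUSP1 rose by 1.75 ± 0.18. The small nucleolar RNA SNORD13 (-5.64 ± 0.28) and the Notch target HES1 (-3.26 ± 0.16) fell.

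The chaperone, serum response and cholesterol lists were called with an estimated correlation (adjusted p = 1.3e-06, 0.0167 and 0.0372, the last with 3 of 17 genes lower and 1 higher, 5 and 1 adjusted over the list alone). In total 519 of 10542 genes rose and 408 fell. The 927 became 436 and 521 without unheated replicate A or B and 335 without heated replicate B, where a group of 1 library was assumed to vary as the others did.

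With sgHSF1.1 the chaperone response was smaller. The interaction term was below 0 for 31 of 31 chaperones and called for 21 (25 adjusted over the list alone). For DNAJB1 it was -3.07 ± 0.16, the response being 1.35 ± 0.12 in sgHSF1.1 cells, for HSPA1A -2.95 ± 0.19, for BAG3 -2.67 ± 0.20, for HSPH1 -2.48 ± 0.18 and for HSP90AA1 -1.73 ± 0.17. Serum response genes had a higher response with sgHSF1.1 in 10 of 18 cases (12 higher and 1 lower adjusted over the list alone). EGR1 stood at 5.33 ± 0.22 and its response turned from a fall to a rise of 2.90 ± 0.16, JUNB, an AP-1 subunit, at 2.23 ± 0.19 and HES1 at 3.47 ± 0.25. The sterol regulator INSIG1 (3.16 ± 0.29) led the cholesterol list, 3 of 17 higher (5 adjusted over the list alone). Unheated sgHSF1.1 cells already held less of these RNAs than cells without a guide, with EGR1 at 40.6 against 365 CPM, HES1 at 38.8 against 321, INSIG1 at 17 against 103 and JUNB at 93.9 against 177. HES1 stood at 44.8 CPM in heated sgHSF1.1 cells and at 32.7 in heated cells without a guide. Of 78 ribosomal protein genes and 56 genes of the COX and NDUF families, chosen after the first results were seen, 30 and 6 were higher and none lower in unheated sgHSF1.1 cells, and 9 and 2 lower and none higher in this interaction (medians -0.29 and -0.18), with camera p = 0.188 and 0.202 in the interaction with an estimated correlation. With an estimated correlation the calls held for chaperones, serum response genes, cholesterol synthesis and replication genes (adjusted p = 1.1e-05, 0.00174, 0.0170 and 0.0282), the last with 3 of 24 lower (4 adjusted over the list alone). The term was called for 294 genes higher and 242 lower. The 536 became 277 without unheated sgHSF1.1 B, 356 and 232 without heated sgHSF1.1 A or B, 285 and 332 without unheated no-guide A or B, and 217 without heated no-guide B.

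In cells labelled sgHSF2.1, whose HSF2 RNA was higher than without a guide in unheated libraries and overlapped it in heated ones, the induction of HSPA1A (-0.35 ± 0.18, adjusted p = 0.197), DNAJB1 (-0.31 ± 0.16) and HSPH1 (-0.18 ± 0.17) did not differ detectably from cells without a guide. HSPE1 (-1.53 ± 0.16), HSP90AA1 (-1.14 ± 0.16) and HSPA8 (-0.97 ± 0.18) responded less. HSPE1 and HSP90AA1 already stood higher in unheated sgHSF2.1 cells, by 0.87 ± 0.12 and 0.92 ± 0.12. Of 31 chaperones 7 were lower and 1 higher (9 and 2 adjusted over the list alone), and of 31 proteasome subunits 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with PSMA3 at -1.37 ± 0.17 and PSMB7 at -1.27 ± 0.16. Serum response genes were higher in 10 of 18 cases and lower in 3 (10 and 4 adjusted over the list alone), EGR1 by 3.97 ± 0.24, and the mitochondrial copper chaperone COX17 was lower (-2.38 ± 0.22). The ribosomal protein genes and those of the COX and NDUF families moved with them: 46 of 78 and 16 of 56 were lower (1 and 0 higher) in this interaction and 45 of 78 and 16 of 56 higher (1 and 1 lower) in unheated sgHSF2.1 cells, with camera p = 0.0550 and 0.0703 in the interaction with an estimated correlation. None of the chaperone, proteasome and serum response lists was called with an estimated correlation (adjusted p = 0.129, 0.154 and 0.129). The term was called for 638 genes higher and 819 lower, and the 1457 became 849 without heated no-guide replicate B. Between the sgHSF2.1 and the sgHSF1.1 responses 148 genes differed, DNAJB1 by 2.76 ± 0.16.

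**Figure D3:**
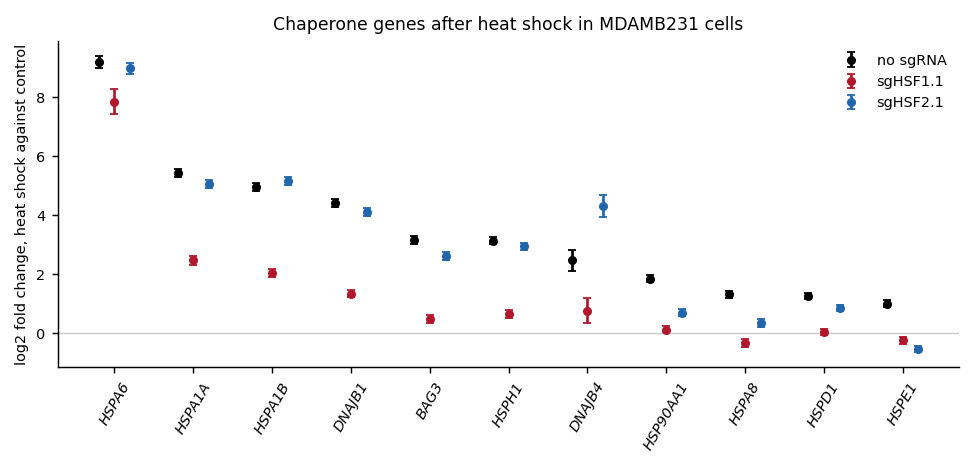
Log2 fold change of chaperone genes between heated and unheated MDAMB231 cells without a guide, with sgHSF1.1 and with sgHSF2.1, with standard errors. DNAJB1 rose by 4.42 without a guide, by 1.35 with sgHSF1.1 and by 4.11 with sgHSF2.1.

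The stress experiment treated MDAMB231 cells with 10 mM 2-deoxyglucose, an inhibitor of glycolysis and glycosylation, with 250 uM cobalt chloride, which stabilises hypoxia-inducible factors, or with serum starvation, to ask how depletion alters each response. Control cells carried a non-targeting guide and siNon-Targeting. HSF1 RNA was 81.8 to 116 CPM in them, 3.72 to 14.3 with siHSF1 alone and 6.54 to 9.70 with siHSF1 in sgHSF2.1 cells. HSF2 RNA was 60.6 to 91.1 CPM in control cells and 63.3 to 100 in the cells labelled sgHSF2.1. Under 2-deoxyglucose ER chaperones rose in 18 of 20 cases (19 adjusted over the list alone), among them HSPA5, the ER HSP70 (2.11 ± 0.070, adjusted p = 2.8e-32), PDIA4 (2.49 ± 0.12) and HYOU1 (2.27 ± 0.11), each in 3 of 3 libraries. ATF4 targets rose in 12 of 18 cases and 1 fell (the same counts adjusted over the list alone), with asparagine synthetase ASNS at 1.94 ± 0.11 and the cystine transporter SLC7A11 at 1.60 ± 0.092, and tRNA synthetases rose in 11 of 18 (12 adjusted over the list alone), with WARS at 1.53 ± 0.11. Mitotic genes fell in 14 of 20 (16 adjusted over the list alone), with AURKA at -0.62 ± 0.085, and proteasome subunits in 10 of 31 (16 adjusted over the list alone). These lists held with an estimated correlation (adjusted p = 5.3e-14, 6.8e-11, 0.000774, 1.3e-06 and 0.000247). In total 567 of 11368 genes rose and 541 fell, and a fit of the compared groups alone called 200.

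Under cobalt chloride 21 of 21 hypoxia targets rose (21 adjusted over the list alone), with the stress gene NDRG1 at 2.47 ± 0.090 and the lipase inhibitor ANGPTL4 at 3.80 ± 0.27. Heme oxygenase HMOX1 rose by 3.18 ± 0.15, the metallothionein MT1X by 2.78 ± 0.13, the cytokine IL6 by 4.23 ± 0.54 and SERPINE1, an inhibitor of plasminogen activation, by 2.38 ± 0.096, each above the 3 control libraries in 3 of 3. ATF4 targets rose in 13 of 18 cases (16 higher and 1 lower adjusted over the list alone), led by SLC7A11 (2.08 ± 0.089). HSP90AA1 (-0.53 ± 0.073) and HSPH1 (-0.45 ± 0.092) fell. Both lists held with an estimated correlation (adjusted p = 3.8e-12 and 6.6e-09), and 1631 genes rose while 1581 fell. A fit of the compared groups alone called 1930 genes, against 3212 in the fit of all groups. Serum starvation raised 18 of 18 cholesterol synthesis genes (18 adjusted over the list alone), with the synthase HMGCS1 at 2.29 ± 0.089 and the reductase HMGCR at 2.08 ± 0.12. Hypoxia targets fell in 10 of 21 cases and 1 rose (13 and 3 adjusted over the list alone), with LDHA at -1.01 ± 0.11 and PGK1 at -0.96 ± 0.070. HSPA1A (1.08 ± 0.15) and BAG3 (0.69 ± 0.13) rose. The 2 lists held with an estimated correlation (adjusted p = 1.5e-15 and 0.000322), and 1302 genes rose while 1482 fell; a fit of the compared groups alone called 1733.

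Each response was then compared between control cells and sgHSF2.1 cells with siHSF1. Under 2-deoxyglucose the response of 4 genes differed. It was higher for HSPA5 (0.78 ± 0.096), the peptide hormone ADM (1.08 ± 0.17) and the stress cytokine GDF15 (1.12 ± 0.20). For the transcription factor KLF6 it was lower (-0.57 ± 0.12). ADM itself stayed lower in sgHSF2.1 cells with siHSF1 than in control cells. It was at 54.8 against 108 CPM under 2-deoxyglucose and at 37.9 against 158 CPM unstressed. The 4 became 88 without unstressed control replicate C and 8 without stressed control replicate B; KLF6 lost its call in 9 of the leave-outs (adjusted p up to 0.256) and in a fit of the compared groups alone (0.970), as GDF15 did there (0.205). Under cobalt chloride the cytokine genes CXCL2 (-2.52 ± 0.32), CXCL8 (-2.06 ± 0.31) and IL1B (-1.90 ± 0.34) responded less, and IL6 (-3.38 ± 0.77) as well, though the IL6 call ended without unstressed sgHSF2.1 with siHSF1 replicate B (adjusted p = 0.0786) or in a fit of the compared groups alone (0.0653). ADM (1.49 ± 0.15), NDRG1 (0.71 ± 0.12) and the kinase PGK1 (0.58 ± 0.096) responded more, from lower unstressed levels of 37.9 against 158 CPM (ADM), 905 against 1198 (NDRG1) and 483 against 705 (PGK1). Under cobalt chloride ADM was at 288 CPM against 423 in control cells, NDRG1 at 8224 against 6673 and PGK1 at 1656 against 1605. Hypoxia targets were higher in 6 of 21 cases (6 higher and 1 lower adjusted over the list alone), also with an estimated correlation (adjusted p = 0.00521). The term was called for 253 genes higher and 202 lower. The 455 became 229 and 217 without stressed control B or C, 200, 272 and 1063 without unstressed control A, B or C, 187 without stressed sgHSF2.1 with siHSF1 A and 205 without unstressed sgHSF2.1 with siHSF1 B, and 69 in a fit of the compared groups alone.

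Serum starvation gave a higher response of ATF4 targets in sgHSF2.1 cells with siHSF1, whose HSF2 RNA overlapped that of control cells, 10 of 18 (12 adjusted over the list alone), with ASNS at 1.48 ± 0.16 and the aminotransferase PSAT1 at 1.14 ± 0.14. ER chaperones were higher in 8 of 20 cases (12 adjusted over the list alone), among them HSPA5 (1.34 ± 0.096), whose response was 1.27 ± 0.068 there, and tRNA synthetases in 10 of 18 (13 adjusted over the list alone), with MARS at 0.94 ± 0.18. GDF15 stood at 1.81 ± 0.19, and HSPA1A (-1.17 ± 0.20) responded less. Cholesterol synthesis genes were lower in 4 of 18 (5 adjusted over the list alone), with HMGCR at -0.69 ± 0.17. These lists held with an estimated correlation (adjusted p = 6.4e-07, 0.00237, 0.000456 and 0.00237). The same term was called for 455 genes with sgHSF2.1 alone and for 5 with siHSF1 alone, where HSPA5 responded by 1.18 ± 0.068 and 0.27 ± 0.076, a difference between these groups that was not tested. The term was called for 335 genes higher and 235 lower. The 570 became 243, 335 and 1309 without unstressed control A, B or C, 352 without starved control A, 307 without unstressed sgHSF2.1 with siHSF1 B and 258 without starved sgHSF2.1 with siHSF1 C; a fit of the compared groups alone called 374.

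MDAMB231 tumours carried sgNon-Targeting (2 tumours), sgHSF1.1 (4) or sgHSF2.1 (4), to ask whether the programme depends on HSF1 and HSF2 in tumours. HSF1 was at 121 and 198 CPM in the controls, 71.2 to 91.8 with sgHSF1.1 and 126 to 149 with sgHSF2.1, and HSF2 at 19.2 and 24.1, 16.7 to 25.2 and 7.75 to 20.3. With sgHSF1.1 S100A4, a calcium-binding protein (1.92 ± 0.22), and SLC7A11 (2.03 ± 0.30) rose and CPVL, a carboxypeptidase, fell by 4.21 ± 0.64, CPVL being named after its values were seen. Of 32 chaperones 28 lay below 0 with none called over all genes (1 lower adjusted over the list alone), a camera call (adjusted p = 5.7e-07) with adjusted p = 0.312 with an estimated correlation. The SLC7A11 call ended without control D (adjusted p = 0.582) or sgHSF1.1 A, B, C or D (0.191, 0.0560, 0.0526 and 0.0547). The 3 genes became 38 without control C and 1 without sgHSF1.1 A, C or D, and DESeq2 called 28. Against the same 2 control tumours, whose values enter both comparisons, S100A4 was the only gene called with sgHSF2.1 (1.81 ± 0.22). The call ended without control D (adjusted p = 0.0710) and in a fit of the compared groups alone (0.192). The count was 17 genes without control C, 0 without control D or in that fit and 2 without sgHSF2.1 C, and 15 by DESeq2. Transcripts encoded in mitochondria lay above 0 in 10 of 13 cases with sgHSF1.1 and 11 of 13 with sgHSF2.1, with none called over all genes or adjusted over the list alone.

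In these MDAMB231 tumours camera called further lists, with no gene of them called over all genes and no list called with an estimated correlation (adjusted p = 0.312 at the lowest with sgHSF1.1 and 0.679 with sgHSF2.1). With sgHSF1.1 mitotic genes (18 of 20 below 0, adjusted p = 1.3e-06, 2 lower adjusted over the list alone), replication genes (21 of 24, 0.000708), hypoxia targets (17 of 21, 0.00380) and CCT (7 of 8, 0.0242) lay lower, and matrix and adhesion genes (19 of 20 above 0, 3.1e-05), serum response genes (13 of 18, 0.0123, 1 higher adjusted over the list alone) and interferon response genes (14 of 19, 0.0242) higher. Calls ended without control C for hypoxia (0.302), CCT (0.214), serum response (0.0569) and interferon (0.0596), without control D for replication (0.472), CCT (0.0872), matrix (0.101), serum response (0.101) and interferon (0.282), and without sgHSF1.1 A for serum response (0.0598), B for hypoxia (0.0760) and interferon (0.238), and C or D for CCT (0.0518 and 0.0939). With sgHSF2.1 chaperones (24 of 32 below 0, adjusted p = 0.00880, 1 lower adjusted over the list alone), hypoxia targets (16 of 21, 0.00204), replication genes (19 of 24, 0.00880) and stromal, endothelial and immune markers (8 of 11, 0.00880) lay lower, and interferon response genes (16 of 19 above 0, 0.00572) and matrix and adhesion genes (14 of 20, 0.00204) higher. Each of these 6 calls ended without 1 of the tumours: control C for chaperones (0.163), hypoxia (0.270) and the markers (0.4656), control D for chaperones (0.0728), replication (0.903, with the direction reversed), interferon (0.181) and matrix (0.706), sgHSF2.1 A for hypoxia (0.130), B for interferon (0.237), C for chaperones (0.106), replication (0.275), interferon (0.162) and matrix (0.102), and D for the markers (0.170).

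PC3M tumours carried no guide (4 tumours), 1 of 2 guides to HSF1 (2 and 2) or 1 of 2 guides to HSF2 (6 and 3). HSF1 was at 887 to 1104 CPM in the controls and 143 to 181 with HSF1 guides. With HSF1 guides 19 of 34 chaperones fell and none rose (22 lower and 2 higher adjusted over the list alone). HSPH1 fell by 2.73 ± 0.27, HSPA4L, an HSP110 relative, by 2.29 ± 0.22, HSPB1 by 2.19 ± 0.20, HSPD1 by 1.49 ± 0.17 and HSPE1 by 1.46 ± 0.16, each below the 4 controls in 4 of 4 tumours. Interferon response genes rose in 7 of 19 cases (10 higher and 1 lower adjusted over the list alone), among them the restriction factor BST2 (5.19 ± 0.85), with adjusted p = 0.186 with an estimated correlation. Of 12 markers of stromal, endothelial and immune cells 4 fell (4 lower and 1 higher adjusted over the list alone), LUM, a matrix proteoglycan, by 5.62 ± 0.91 and the collagen COL1A2 by 0.88 ± 0.18. The tumours of both lines grew in mice, and the notes describe alignment to hg38. Whether reads of these markers came from human or mouse cells was not tested in any tumour. The chaperone call held with an estimated correlation (adjusted p = 0.0143), and 639 genes rose while 851 fell. Of 13 transcripts encoded in mitochondria 10 lay below 0 and 1 was called, MT-ATP8 (-0.74 ± 0.22, adjusted p = 0.0372; 1 lower adjusted over the list alone), and the list was not called (adjusted p = 0.0703). The MT-ATP8 call ended without control B, C or D (0.0694, 0.0892 and 0.0558), sgHSF1.1 tumour 1 (0.108) or sgHSF1.2 tumour 1 or 2 (0.0506 and 0.0806). The 1490 became 926 without the sgHSF1.1 tumour 2.

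With HSF2 guides, HSF2 was at 16.3 to 23.4 CPM with sgHSF2.1 and at 57.4 to 64.9 in the tumours labelled sgHSF2.2, against 28.3 to 33.1 in the controls. Tumours with HSF1 guides also held less HSF2 than the controls, at 20.4 to 25.4 CPM. With HSF2 guides, HSF1 was at 874 to 1030 CPM with sgHSF2.1 and at 714 to 858 with sgHSF2.2, against 887 to 1104 in the controls. Here 1000 genes rose and 947 fell, with BST2 at 6.07 ± 0.80, the protease inhibitor PI3 at 4.47 ± 0.48 and the adhesion protein TNS4 at 3.34 ± 0.44 among the rises and the proteoglycan VCAN (-3.30 ± 0.67) and LUM (-2.54 ± 0.53) among the falls, in 9 of 9 tumours. Of 34 chaperones 4 rose and 1 fell (the same counts adjusted over the list alone), HSPA6 standing at 1.62 ± 0.34 and HSPE1 at -0.66 ± 0.13, and of 12 stromal, endothelial and immune markers 3 fell (4 lower and 2 higher adjusted over the list alone). Transcripts encoded in mitochondria lay below 0 in 7 of 13 cases, with none called over all genes or adjusted over the list alone. The ubiquitin gene UBC (0.88 ± 0.16), which is 1 of the 4 rises counted in the chaperone list, and the pseudokinase TRIB3 (1.81 ± 0.31) rose. The 1947 became 1255 without control A, and 4177 with sgHSF2.1 alone and 3140 with sgHSF2.2 alone; between these guides 4072 genes differed. Across 15153 genes the fold changes under HSF1 and HSF2 guides had r 0.748, against a simulated mean of 0.589 from the shared controls, and a covariance of 0.488 against 0.0744. Both comparisons called 360 genes higher (42.2 by chance for independent lists) and 348 lower (53.2), with 0 in opposite directions. With the 4 control tumours split between the comparisons r lay between 0.296 and 0.671.

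MCF7 cells expressed HSF1-Flag, HSF2-Flag or GFP-Flag, to ask which genes respond to more of each factor. HSF1 RNA was 83.2 to 89.0 CPM with HSF1-Flag and 80.8 to 88.4 with GFP-Flag. HSF2 RNA was 37.4 to 57.0 CPM with HSF2-Flag, 39.2 to 48.2 with HSF1-Flag and 32.6 to 37.8 with GFP-Flag. Neither construct gave a call of HSF2 (adjusted p = 0.216 with HSF1-Flag and 0.0728 with HSF2-Flag). Reads from the 3' end do not cover a construct that lacks the gene's own 3' end. With HSF1-Flag 16 of 20 interferon response genes fell (16 adjusted over the list alone), with IFI44L at -3.47 ± 0.20, IFI27 at -3.07 ± 0.17 and OAS2 at -2.80 ± 0.20, and the stem cell factor SOX2 (2.62 ± 0.25) and the neural factor ASCL1 (2.09 ± 0.14) rose, in 3 of 3 libraries. Chaperones rose in 6 of 31 cases and 1 fell (10 and 2 adjusted over the list alone), HSPA1A standing at 0.85 ± 0.12 and HSP90AA1 at -0.46 ± 0.090, while proteasome subunits fell in 10 of 31 (16 adjusted over the list alone), with PSMA4 at -0.57 ± 0.086. Interferon, chaperone and proteasome lists held with an estimated correlation (adjusted p = 0.000181, 0.0243 and 0.00180). In total 607 of 12222 genes rose and 634 fell. The 1241 became 721 and 826 without GFP-Flag B or C and 683 without HSF1-Flag B.

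With HSF2-Flag serum response genes rose in 7 of 17 cases (9 adjusted over the list alone), including JUN (0.75 ± 0.11) and JUNB (0.95 ± 0.12), and p53 targets in 3 of 15 (4 higher and 2 lower adjusted over the list alone), led by GDF15 (1.21 ± 0.12). Mitotic genes fell in 7 of 20 and 1 rose (11 and 1 adjusted over the list alone), with TOP2A at -0.68 ± 0.10. HSPB8, a small heat shock protein, rose by 2.36 ± 0.54 and HSP90AA1 fell by 0.63 ± 0.090. Of 22 extracellular matrix and adhesion genes 17 were measured and 1 rose, TGFBI by 1.04 ± 0.22 (1 adjusted over the list alone). The serum response, p53 and mitotic lists held with an estimated correlation (adjusted p = 0.0196, 0.0196 and 0.0125). In total 811 genes rose and 821 fell, and the 1632 became 883 without GFP-Flag B and 1032 without HSF2-Flag C. The fold changes under HSF1-Flag and HSF2-Flag, which share controls, had r 0.400 against 0.502 in simulations without effects, with a covariance of 0.0728 against 0.0349. They shared 240 rises (40.3 by chance for independent lists), 224 falls (42.6) and 39 opposite calls. The shared controls make these lists dependent, so the counts do not separate shared regulation from the shared controls. No gene was called in edgeR or DESeq2 between the HSF1-Flag response under siHSF2, or the HSF2-Flag response under siHSF1, and that under siNon-Targeting (557 and 722 at unadjusted p under 0.05), and 5 and 48 were called without the low-count filter. Camera called hypoxia targets (16 of 19 above 0) and interferon response genes (15 of 20) higher in the HSF1-Flag response under siHSF2 (adjusted p = 0.0126 for both), with no gene of them called over all genes or adjusted over the list alone and adjusted p = 0.426 and 0.528 with an estimated correlation. The hypoxia call ended without GFP-Flag siHSF2 B (0.157), GFP-Flag siNon-Targeting A (0.156), HSF1-Flag siHSF2 A (0.275) or HSF1-Flag siNon-Targeting B (0.0647), and the interferon call without GFP-Flag siHSF2 B (0.155), HSF1-Flag siHSF2 B (0.6, with the direction reversed) or HSF1-Flag siNon-Targeting B (0.382) or C (0.0601).

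**Figure D4:**
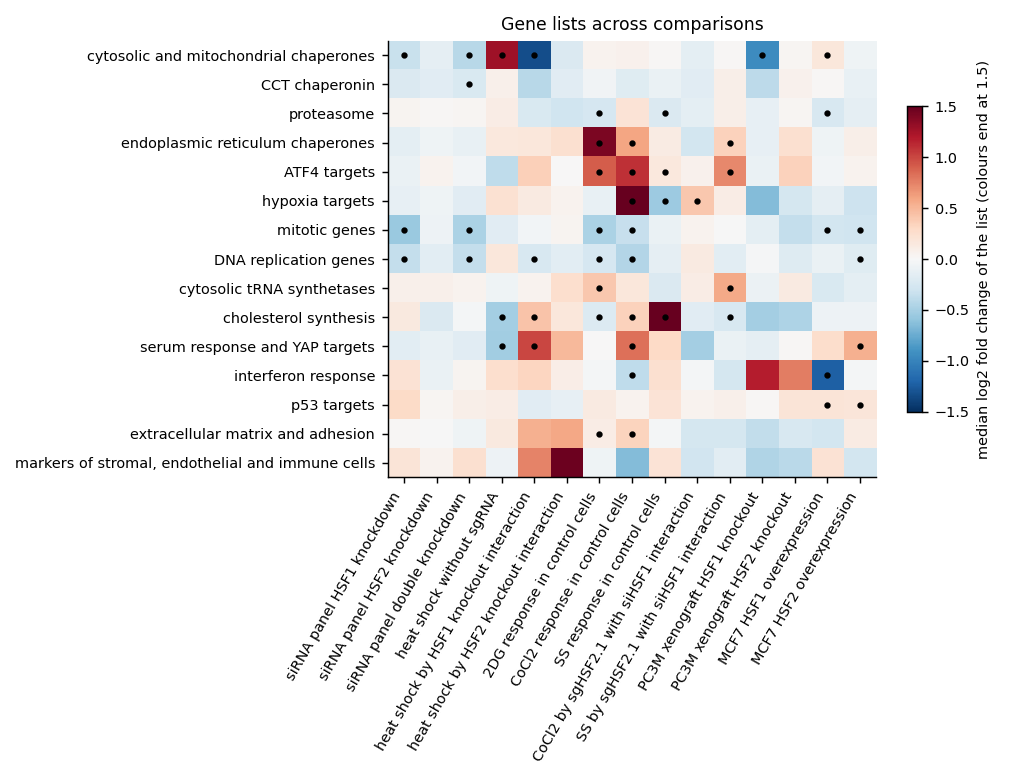
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), with colour giving the size and direction. The chaperone list lay at 1.27 under heat without a guide and at -0.334 under siHSF1.

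The ChIP-seq peak lists gave positions on hg38 for HSF1 and HSF2 in MDAMB231 and in PC3M clones X1 and X2, with 2 lists per antibody in cells without a guide. In MDAMB231 the lists held 2945 and 1607 HSF1 peaks and 871 and 2007 HSF2 peaks. PC3M X1 lists held 2485 and 9436 HSF1 peaks and 479 and 903 HSF2 peaks, and X2 lists 7349 and 7731 HSF1 peaks and 5883 and 3934 HSF2 peaks. Peaks present in both lists formed 441 HSF1 and 461 HSF2 regions in MDAMB231, 1505 and 84 in X1 and 3259 and 788 in X2. The share of these regions within 1 kb of a transcription start site was 5.22% (exact 95% interval 3.33% to 7.72%) for HSF1 in MDAMB231, against 71.4% in X1 and 68.5% in X2, and 5.42%, 75.0% and 65.1% for HSF2. In single lists it was 2.11% and 5.41%, 50.2% and 68.7%, and 47.7% and 57.4% for HSF1, and 3.56% and 3.39%, 67.6% and 20.6%, and 59.7% and 28.1% for HSF2. MDAMB231 replicate lists overlapped in 15.1% of HSF1 list A and 27.9% of list B.

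HSPD1 and HSPE1 lie head to head on chromosome 2 and share a promoter, with HSPD1 from 197486584 to 197500274 on the minus strand and HSPE1 from 197499997 to 197503463 on the plus strand. In MDAMB231 an HSF1 peak covered it from 197499331 to 197500911 and an HSF2 peak from 197499622 to 197500661 in lists A. PC3M X1 had an HSF2 peak there in both lists and no HSF1 peak, and X2 had both. HSPA8 on chromosome 11 had an MDAMB231 HSF1 peak from 123061369 to 123062905 over its start site at 123062335. DNAJB1 on chromosome 19 (14514764 to 14518559) had peaks for both factors in PC3M and none in MDAMB231. Of 34 chaperone genes, HSF1 regions lay within 1 kb of the start site of 4 in MDAMB231 (HSPA8, HSPD1, HSPE1 and the ubiquitin gene UBB), 16 in X1 and 25 in X2, and HSF2 regions of 6, 19 and 22. In X2 7 of 8 CCT subunits had an HSF1 region and 8 of 8 an HSF2 region, and 1 and 0 of 31 proteasome subunits.

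Whether the factors share sites was asked by overlap. In MDAMB231 242 of 461 HSF2 regions overlapped an HSF1 region (52.5%, 47.8% to 57.1%), in X1 67 of 84 (79.8%, 69.6% to 87.7%) and in X2 459 of 788 (58.2%, 54.7% to 61.7%), with exact intervals. Random placement gave mean shares of 0.0236%, 0.126% and 0.383%, and each one-sided permutation p was 0.000999, the smallest that 1000 placements can give. Lists whose regions gather at the same kinds of sites, such as start sites, would exceed random placement whatever the antibody. The p therefore does not separate sites shared by the factors from such gathering. These shares moved when a region had to be in either list rather than both, to 24.8%, 39.3% and 40.5%, and with a replicate list alone, to 34.7% and 21.9%, 28.4% and 25.1%, and 34.3% and 26.4%. In cells labelled sgHSF2.1 388 of 441 HSF1 regions of MDAMB231 were found again in a merged list of 2076 peaks (88.0%, 84.6% to 90.9%), and in cells labelled sgHSF1.1 191 of 461 HSF2 regions in a merged list of 648 peaks (41.4%, 36.9% to 46.1%). The HSF1 share fell to 21.7% with peaks of either list, 20.7% with list A and 42.3% with list B, and the HSF2 share to 9.86%, 23.5% and 11.1%. None of the 8 chaperone genes fixed beforehand had a peak within 1 kb in these merged lists, against 3 and 4 in the HSF1 lists A and B of cells without a guide.

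Genes near regions bound by each factor in MDAMB231 were set against other genes in the siRNA panel. The fold changes were those of the fit of all 11 lines, not of MDAMB231 alone. Of 34 genes within 1 kb of an HSF1 region 19 were tested, 4 fell and 0 rose under siHSF1, with a median of -0.17 against 0.03 for other genes (camera adjusted p = 0.00294, and adjusted p = 0.0566 with an estimated correlation). Of 40 genes near an HSF2 region 26 were tested, 3 fell and 0 rose under siHSF2, with a median of -0.13 against 0.01 (adjusted p = 1.7e-05, and 0.0156 with an estimated correlation). With PC3M X1 regions the adjusted p was 0.228 for HSF1 and 2.2e-07 for HSF2, and with X2 regions 0.163 for both.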

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

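Tests chosen only after the result was seen were those for another cell line and for the named knockouts in the first pattern, where the baseline of the batch test was also set afterwards, for clones and for shared controls as the whole cause in the second, and the comparison of list sizes in the third; the others were written before.

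Among 45 groups tested for a sample far from the others 3 stood out, and chance alone gives about 1 in 20 groups. HSF1 in the CRISPR panel changed by -3.84 in PC3M against a median of -1.78 in the other lines of the 6. HSPA1A under HSF2 guides stood at -2.38 in LNCaP against -0.157. HSPE1 under both siRNAs stood at -1.56 in BT20 against -0.756 in the other lines of the 7.

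A test of the interaction itself called 536 genes for heat with sgHSF1.1 and 1457 for heat with sgHSF2.1. The heat groups hold 2 libraries each, too few for other splits of the samples. In sgHSF2.1 cells with siHSF1, whose HSF2 RNA overlapped that of control cells, it called 4, 455 and 570 genes for 2-deoxyglucose, cobalt chloride and serum starvation. Of 40 splits of the same samples 17, 10 and 7 called as many. These splits exchanged libraries between treatments and between control and depleted cells, so the effects of both entered the term. They cannot decide whether chance gave these counts.

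The first pattern is the distance of 3 MDAMB231 knockout libraries (sgHSF1.1 B and both guides B and C) from the other 9, with EEF1A1 at 9.92 to 10.87 against 6.50 to 7.93 log2 CPM and HSF2 at 6.18 to 6.62 against 3.07 to 4.95. Libraries of another cell line were excluded: the 3 reached at most r 0.800 with controls of another line, against at least 0.963 with their own. The knockouts their labels name were excluded as the whole cause, since other libraries of the same groups reached at most 24 CPM of HSF2. Another library preparation or batch remains a candidate explanation: the shift from the 6 of the other libraries that are not sgAAVS1 had r 0.594 across genes with the difference between the stress table and sgAAVS1, against 0.419 for the heat table and 0.00855 for the siRNA table, where the 10 splits of these 6 libraries into 3 and 3 gave at most 0.0785, 0.161 and 0.217 in size. No label records a batch, and a mislabelled library from another MDAMB231 experiment could give the same values.

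The second pattern is the set of genes that move the same way in PC3M tumours with HSF1 guides and with HSF2 guides (r 0.748, 360 higher and 348 lower in both). A difference between clones X1 and X2, as measured in culture, was argued against: over 558 of these genes their mean change in tumours had r 0.0360 with the clone difference, whose 2 replicates had r 0.248 with each other. The labels do not give the clone of any tumour, so a difference between other clones, or one seen only in tumours, stays open. Shared control tumours were argued against as the whole cause: with different controls in the 2 comparisons the covariance kept at least 68.3% of its 0.488 in each of the 6 splits (0.333 to 0.601); what they add to r cannot be told apart from the rest, since r lay between 0.296 and 0.671 over these splits and 139 and 90 genes were called in opposite directions in 2 of them. Loss of HSF1 or HSF2 stays open, with 58.5% of the genes called under siHSF1 (563 of 962) having the same sign in tumours with HSF1 guides. So does an effect of carrying any guide, since 0 of 17 tumours had a non-targeting guide.

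The third pattern is the persistence of MDAMB231 regions in cells of the other factor's guide. For HSF2 a weaker peak list in the edited cells remains a candidate explanation for the lost regions: their median score was lower than that of kept regions (difference -107, 110 against 217), and the merged list held 648 peaks over 154938 bp against 871 and 2007 peaks over 589626 and 1007099 bp. For HSF1 this cannot be told apart: the lost regions had a lower median score (difference -51.8, 78.5 against 130), but the merged list held 2076 peaks over 2207091 bp, against 2945 and 1607 peaks over 1561509 and 772492 bp, and a list merged from several samples is not on the same footing as single ones. Regions called whatever the antibody cannot be told apart: of the regions also found in PC3M X2, 22 of 26 HSF1 regions were kept against 366 of 415 others (Fisher's exact p = 0.537), and 3 of 14 HSF2 regions against 188 of 447 (Fisher's exact p = 0.170). These p do not show that the shares were equal, and no test separated the antibodies themselves.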

How the results depend on the processing

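Tests chosen after the data were seen were the omission of the 3 MDAMB231 libraries that stand apart, peaks near start sites alone and the exchange of control sets. Of 180 values of comparisons under other settings 108 were the same within the limits used, 68 moved and 4 lost their call. Of 250 values with a library or line left out 182 were the same and 68 moved. For named genes 11627 of 12969 values were the same, 1260 lost their call, 82 gained it and 0 reversed, and for gene lists 4905 of 5278 were the same, 191 lost the call, 180 gained it and 2 reversed. The reversals were the replication list in MDAMB231 tumours with sgHSF2.1 without the control tumour D (0.00963, with a range of -0.366 to 0.00963 over left-out tumours) and the interferon list in the HSF1-Flag by siHSF2 interaction without HSF1-Flag siHSF2 replicate B (-0.0779, with a range of -0.0779 to 0.379). The cause was not tested for any change below unless stated.

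With DESeq2 the counts became 184 for HSF2 knockdown, 506 for the double knockdown (190 higher, 37.5%, against 53, 24.9%), 2 for double against HSF1 knockdown and 21 for HSF1 guides in the CRISPR panel. In MDAMB231 knockout cells they became 4 (sgHSF1.1), 7 (sgHSF2.1), 567 (both guides, 75.5% higher) and 5 (departure from additivity). They became 569 for heat, 326 and 954 for its interactions with sgHSF1.1 and sgHSF2.1, and 28 (78.6% higher) and 15 (66.7% higher) for HSF1 and HSF2 guides in MDAMB231 tumours. With RLE factors no comparison's count moved by over 1.5 times.

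Without the low-count filter the counts became 173 (HSF2 knockdown), 110 and 48 (HSF1 and HSF2 guides in the CRISPR panel), 3, 3, 291 and 1 (MDAMB231 sgHSF1.1, sgHSF2.1, both guides and non-additivity), 7 (2-deoxyglucose by sgHSF2.1 with siHSF1), 263 and 148 (MDAMB231 tumours with HSF1 and HSF2 guides), and 5 and 48 (HSF1-Flag by siHSF2 and HSF2-Flag by siHSF1).

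With each library as a replicate, which adds replicates of the same line, the counts became 2329 (HSF1), 402 (HSF2), 2020 (HSF1 against HSF2), 1393 (double), 40 (double against HSF1), and 140 and 10 (HSF1 and HSF2 guides). HSF2 knockdown gave 161 with 13 models, and HSF1 guides 13 with sgHSF1.1 and sgHSF2.1 alone. A fit of the compared groups alone, with fewer samples, gave 200 (2-deoxyglucose), 1930 (cobalt chloride), 1733 (serum starvation), 2, 69 and 374 (their interactions in sgHSF2.1 cells with siHSF1) and 0 (MDAMB231 tumours with sgHSF2.1). PC3M tumours gave 4177 with sgHSF2.1 and 3140 with sgHSF2.2. Without the 3 libraries that stand apart MDAMB231 knockouts gave 3 (sgHSF1.1), 4 (sgHSF2.1), 0 (both guides) and 1 (non-additivity).

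With replicate letters as a block MDAMB231 cells with sgHSF2.1 gave 1 gene and MDAMB231 tumours with sgHSF2.1 gave 0. Under this pairing 687 of 697 values of named genes and 277 of 287 of lists were the same. The calls of SLC7A11 in MDAMB231 tumours with sgHSF1.1 (adjusted p = 0.0780) and of S100A4 in those with sgHSF2.1 (0.0525) ended under it. So did the camera calls of the hypoxia list in these tumours (adjusted p = 0.107 with sgHSF1.1 and 0.0601 with sgHSF2.1). No paired analysis was made for PC3M tumours, although their sample titles carry letters. The columns of the tumours with HSF1 guides and of part of those with sgHSF2.1 bear names that also match samples of cultured cells, so they were used by group without their letters. The letters of the remaining tumours do not recur between the groups compared.

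Leaving out 1 line or library gave these ranges: HSF1 knockdown 653 to 1147, HSF2 knockdown 16 to 80, HSF1 against HSF2 484 to 982, double knockdown 73 to 148, double against HSF1 1 to 1, siRNA non-additivity 0 to 0, CRISPR panel 2 to 6 (HSF1) and 0 to 0 (HSF2). MDAMB231 knockouts gave 1 to 1 (sgHSF1.1), 0 to 0 (sgHSF2.1), 0 to 2067 (both) and 0 to 1 (non-additivity). Heat gave 335 to 645, with sgHSF1.1 217 to 496 and with sgHSF2.1 849 to 1428, where a lone library was assumed to vary like the other groups. Stress gave 749 to 1468 (2-deoxyglucose), 2570 to 3245 (cobalt chloride) and 1946 to 2968 (serum starvation), and in sgHSF2.1 cells with siHSF1 3 to 88, 187 to 1063 and 243 to 1309. MDAMB231 tumours gave 1 to 38 (HSF1) and 0 to 17 (HSF2), PC3M tumours 926 to 1372 and 1255 to 2346. Overexpression gave 683 to 1009 (HSF1-Flag), 883 to 1376 (HSF2-Flag) and 0 to 0 for both interactions.

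The share of HSF2 regions that overlap HSF1 regions became 24.8% (MDAMB231), 39.3% (X1) and 40.5% (X2) with peaks of either list. With a replicate list alone it became 34.7% and 21.9% (MDAMB231 A and B), 28.4% and 25.1% (X1 A and B) and 34.3% and 26.4% (X2 C and D), and 67.0% in X2 with the better scored peaks of each list (the upper 50%). The share of HSF1 regions kept with sgHSF2.1 became 21.7% (either list), 20.7% (A) and 42.3% (B). That of HSF2 regions kept with sgHSF1.1 became 9.86%, 23.5% and 11.1%, and 32% near start sites alone. Genes bound by HSF1 had p 0.0566 with an estimated correlation, 0.228 with X1 regions and 0.163 with X2 regions, and genes bound by HSF2 0.163 with X2 regions. The correlation of HSF1 and HSF2 fold changes was 0.189 to 0.244 with a line left out, 0.390 with shared controls, 0.313 among genes with a mean log2 CPM of at least 5 and 0.225 with the control sets exchanged.

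The smallest libraries held 468215 counts in the siRNA panel and 580681 in the CRISPR panel, and the effect of depth on the calls was not tested. In simulated MDAMB231 knockout cells 9 of 100 genes changed by 2-fold were recovered, and the reason for this low share was not tested.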

Other observations

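The tests of other splits of the samples in this part were planned, and the further contrasts were chosen after the first results were seen.

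Chance was excluded for HSF1 knockdown (1 of 40 splits called as many genes, 1045 against at most 1 in the others), HSF2 knockdown (1 of 40, 60 against 4), HSF1 against HSF2 knockdown (1 of 40, 938 against 717), and the double knockdown (1 of 40, 213 against 15). For double against HSF1 knockdown (1 of 40, 1 against 0) the gene called was HSF2, the target of the added siRNA, so this count says nothing of a response. For HSF1 guides in the CRISPR panel the share was also under 0.05 (1 of 32, 7 against 3), the smallest that 32 splits can give. HSF1, the target of the guides, was 1 of the 7 genes. The real split also called the most genes for PC3M tumours with HSF1 guides (1 of 35, 1490 against 183) and HSF2 guides (1 of 100, 1947 against 1269). These splits treat tumours as exchangeable, while 4072 genes differed between tumours of the 2 HSF2 guides. Chance differences between the cells that formed each group of tumours were therefore not excluded.

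For interactions in sgHSF2.1 cells with siHSF1 the splits mixed treatments and depletions, whose own effects enter the term, so they cannot decide about chance. As many genes were called in 17 of 40 splits for 2-deoxyglucose (4 against 2153), 10 of 40 for cobalt chloride (455 against 1321) and 7 of 40 for serum starvation (570 against 2676). Where the real count is 0, each split calls as many by construction and the test decides nothing. This holds for HSF2 guides in the CRISPR panel (32 of 32, 0 against 0), the departures from additivity in the siRNA panel (40 of 40, 0 against 146) and in MDAMB231 knockouts (100 of 100, 0 against 2282), and the HSF1-Flag and HSF2-Flag interactions (100 of 100 each, 0 against 739 and 0 against 498). Splits of such terms exchanged libraries between all groups of the term, so differences between single groups can enter and a split can call several times the real count.

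With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: HSF1-Flag 1241 (highest other 0), HSF2-Flag 1632 (0), MDAMB231 sgHSF1.1 1 (0), sgHSF2.1 0 (0; 10 splits as large), both guides 1 (0), 2-deoxyglucose 1108 (1295; 2 splits as large), cobalt chloride 3212 (432) and serum starvation 2784 (30).

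Before stress was added, 287 genes differed between control and siHSF1 MDAMB231 cells, 1726 between control and sgHSF2.1 cells and 2309 between control cells and sgHSF2.1 cells with siHSF1, named by their labels since their HSF2 RNA overlapped that of control cells. At control temperature sgHSF1.1 cells differed from cells without a guide in 1459 genes and sgHSF2.1 cells in 1715. In MCF7 cells with GFP-Flag, siHSF1 changed 337 genes, siHSF2 20 and both 1392.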
